A study of Mus musculus with 2 samples.

How the data were processed

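Gene expression was measured in interdigital tissue of mouse hind limbs at embryonic day 13.5 in wild-type C57BL/6 (B6) embryos and in embryos homozygous for Hammer toe, on Affymetrix arrays, which read each transcript through sets of short oligonucleotide probes. Per the labels' protocols, total RNA was isolated on RNeasy columns and biotinylated cRNA was made from 250 ng of it. The deposited table gives 1 intensity per probe set and array on a linear scale, which the authors made with MAS5 in Affymetrix Expression Console, per the submitters' processing notes, with no version given. MAS5 combines the perfect-match and mismatch probes of a probe set into a single value and then scales each array. The deposited intensities bear this out: the mean of each array with 2% trimmed at each end was 500.003 on both arrays. This scaling sets the arrays to a common level, so a change of most transcripts in the same direction cannot be seen. No detection calls were used here.

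There were 45101 probe sets, of which 64 were control probe sets and stayed out of the gene comparison. GEO's platform annotation, with symbols matched to the RefSeq gene table of GRCm38.p6 through the gene ID, gave exactly 1 gene to 34945 of the other 45037 probe sets. It gave several genes to 932 and none to 9160. For 204 of the probe sets with 1 gene, the gene ID had no match in the table and the annotation's symbol was kept. The RefSeq table was used only for names and for the order of genes along the chromosome around Shh, and no coordinates from it are given.

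Low MAS5 intensities were taken to be mostly noise. A floor was therefore set at the median of all non-control values of both arrays, an intensity of 78.1. This floor is a choice and not a measured background: unspiked control probe sets read 1.05 to 5.94, well under it. Values under the floor were raised to it before the log2 ratio, Hammer toe over wild type, was taken. A gene counted as measured when its brighter array was above the floor, which left 11621 of 18193 named genes. Where the dimmer array was at or under the floor, the ratio is only a lower bound and is written as "at least". A gene was read from its probe set with the highest mean over both arrays, so counts of list members at 1.5-fold or 2-fold refer to that probe set. Other measured probe sets are quoted for many of the genes named, not for all.

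With 1 array per genotype there was no test, and no p-value was computed. Genes were called different by size alone, at 2-fold or more. Spread was judged in 3 ways: from the spiked hybridisation controls, from the disagreement between probe sets of the same gene (5134 genes with more than 1 probe set above the floor on both arrays), and from the spread of all genes at the same intensity. The first 2 measures leave out the variation between embryos or litters. The third compares the 2 samples themselves, so it mixes technical spread with differences between embryos, sexes and genotypes and cannot separate them. Each of 22 gene lists was summarised by the median log2 ratio of its measured members. The median was placed among the medians of 10000 random lists of the same size, drawn from measured genes in 20 bins of mean expression. Its standard error came from 2000 bootstrap draws of the members. The percentile describes these arrays and is not a p-value, since genes are not replicates and list members can move together. With 22 lists, about 1.1 would lie outside the middle 95% by chance if members were independent.

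The lists, the floor, the size of change, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Shh and all measured hedgehog targets, the members of every other list at 2-fold or more (at most 6, or the largest where none reached it), the 12 genes furthest apart in each direction with both arrays above the floor and no opposed probe sets among those above the floor on both arrays, and the 5 largest bounds in each direction. Further list members are quoted as examples and were chosen after their values were seen. List members missing from the counts were under the floor on both arrays, and enter only some alternatives with a lower floor or none, or were not analysed here because no probe set named them alone. The alternatives were median centring, quantile normalization, a lowess correction for intensity (span 0.3), no floor, floors at the 25th and 75th percentile, a pseudocount in place of the floor, the mean over probe sets, leaving out probe sets with the suffixes _x_at, _s_at and _a_at, other sizes of change and a demand that all of several probe sets pass.

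The script was tested on simulated data in which the observed log2 ratios were shuffled among probe sets of similar intensity and 200 of the 18193 genes were changed. All 50 genes raised 4-fold and all 50 lowered 4-fold were called. Of the genes changed 2.83-fold, 46 of 50 raised and 45 of 50 lowered were called. Among 11191 measured genes left unchanged, 40 passed 2-fold, as their shuffled ratios include the real ones. Of 200 random lists of 15 genes, 9 fell outside the middle 95%. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.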

Results

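Hammer toe is a mouse mutant with webbed digits, and the comparison asks which transcripts differ in the tissue between the digits when interdigital regression is due. The data consist of 1 array of wild-type and 1 array of homozygous Hammer toe hind limb interdigital tissue from mid-gestation embryos. The study design speaks of 3 sets of 5 littermates, 15 embryos in each genotype, but the values used here come from a single array per genotype. How the sets relate to that array is not stated. The genotype labels name B6 only for the wild type, so a difference of strain cannot be told apart from the Hammer toe genotype. Both arrays had the same scaled mean, with median intensities of 78.1 in wild type and 78.5 in Hammer toe. There were no replicates, so no value below has an error between samples. The number of arrays limits the precision.

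Shh and its pathway targets Hhip and Gli1 were higher on the Hammer toe array, by at least 2.45-fold, 3.75-fold and 1.82-fold. Cartilage genes were lower in 14 of 16, with Sox9 at a log2 ratio of -0.64 and Col2a1 at -0.67. The matrix proteoglycan genes Ogn and Lum and the Wnt antagonist gene Dkk1 were 2.73-fold, 2.64-fold and 2.53-fold higher. BMP signalling and cell death genes stayed within 1.5-fold on their brightest probe sets, except that Nog and Chrd gave only lower bounds. A second probe set of Smad7 had a log2 ratio of -1.71. Most other genes were closely similar. Across the 21517 probe sets above the floor on both arrays, the log2 intensities correlated with Pearson's r of 0.991 across probe sets, which are not independent replicates. Of 11621 measured genes, 96.4% had a ratio under 1.5-fold, and the median log2 ratio was 0.01. Genes with 1 array under the floor entered this share at their lower bound, so some of them may differ by more. At least 2-fold higher in Hammer toe were 30 genes, and at least 2-fold lower were 13. The genes that stood furthest above wild type included matrix and secreted proteins. Ogn (osteoglycin, a small proteoglycan of the matrix) read 433 in wild type and 1181 in Hammer toe, 2.73-fold higher, and both of its probe sets were higher, by log2 ratios of 1.45 and 1.89. Lum (lumican, a related proteoglycan) was 2.64-fold higher, from 556 to 1465. Dkk1, a secreted Wnt antagonist, was 2.53-fold higher, from 741 to 1873, and its second probe set had a log2 ratio of 1.44. Sbspon, a secreted matrix protein, was 2.49-fold higher and Apod, a lipocalin, 2.71-fold higher. The second probe set of Sbspon had a log2 ratio of 0.83, and that of Apod, under the floor in wild type, of at least 0.15. Smaller signals gave Ptchd4, Arsi, Dlk1, Tinagl1 and Atp6v0a1 at 2.27-fold to 2.57-fold. Ptchd4 and Atp6v0a1 each had another probe set with the opposite sign, under the floor in Hammer toe, with bounds of -0.52 and -0.27 on the log2 scale. Among genes above the floor on both arrays, the largest ratio was that of Macroh2a3, 4.53-fold higher, which rested on a single probe set of the _x_at type, a type that can bind related transcripts.

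Among the genes furthest below wild type, Tmem63b was 3.11-fold lower, from 373 to 120, and Ces5a 2.86-fold lower. Cdk20 was 2.47-fold lower and Afp (alpha-fetoprotein, a serum protein of the embryo) 2.36-fold lower. Ces5a rested on a single measured probe set of the _x_at type and Cdk20 on a single one of the _s_at type. Neither gene was measured when such probe sets were left out. Tspan32, Tubb1, Tpbgl, Kcnt2, Tox, Rasgrp2, Gja3 and Arhgap39 were 2.05-fold to 2.26-fold lower. For Tox, Rasgrp2 and Arhgap39, the measured probe set nearest to no difference had log2 ratios of -0.08, -0.41 and -0.23. The other measured probe sets of Afp were under the floor in Hammer toe, with bounds of -0.88 and -0.04. Where 1 array was under the floor, the largest bounds were those of Pkp1 (a desmosome protein, at least 2.66-fold higher), Mgmt (at least 2.62-fold), Krt19 (a keratin of epithelia, at least 2.53-fold), Shh (at least 2.45-fold) and Tafa5 (at least 2.30-fold). In the other direction Fbxo44, Cog5, Nrxn3, Ebf4 and Trim46 were at least 1.99-fold, 1.99-fold, 1.95-fold, 1.91-fold and 1.83-fold lower.

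The spread between the arrays depended on intensity. The 18 spiked hybridisation control probe sets had log2 ratios with an SD of 0.06, while probe sets of the same gene disagreed with an SD of 0.21. Among genes whose brighter array read up to 200, 95% lay within 1.60-fold, against 1.45-fold between 200 and 1000 and 1.24-fold above 1000. Genes with 1 array under the floor were again taken at their bound. Of the 43 genes at 2-fold or more, 28 had a single measured probe set, and 11 of the other 15 had all measured probe sets on the same side. Only for Dkk1 and Ogn did every measured probe set, of 2 or more, pass 2-fold, with bounds counted at their bound. The counts depended on the floor: with a floor at the 25th percentile of all values, 397 genes were higher and 385 lower.

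**Figure D1:**
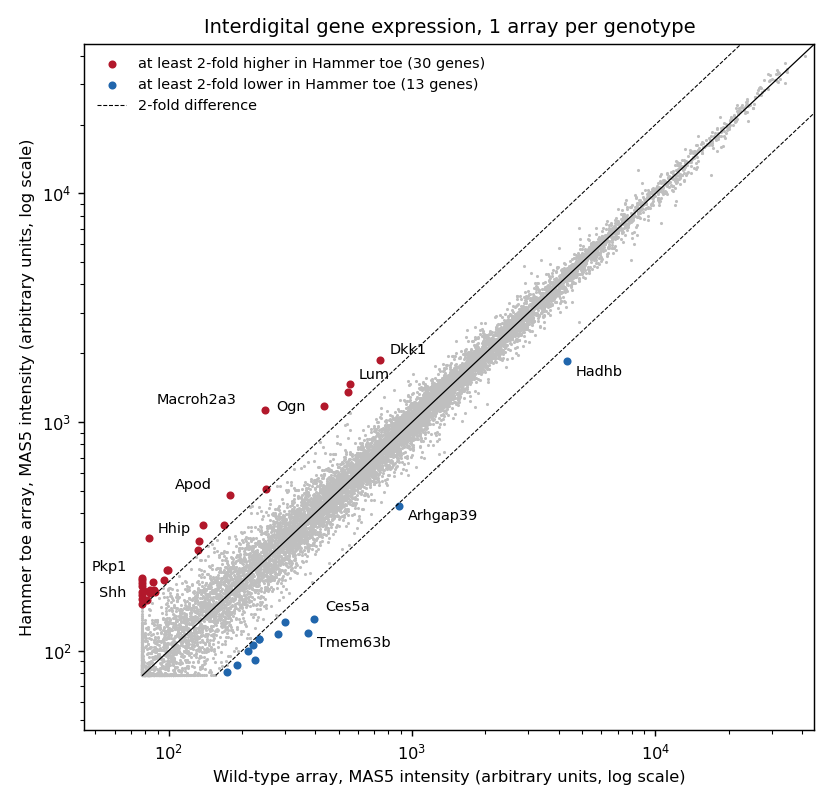
Each point is a measured gene, placed by its MAS5 intensity on the wild-type array (x axis) and the Hammer toe array (y axis), both in arbitrary units on log scales, with values under the floor of 78.1 drawn at the floor. The solid line marks equality, the dashed lines 2-fold differences, and the 30 higher (red) and 13 lower (blue) genes lie outside them, most of them under an intensity of 1000 on both arrays.

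Hedgehog signalling genes included some of the largest differences. Shh, the secreted ligand that patterns the limb, read 22.5 in wild type, under the floor, and 192 in Hammer toe, at least 2.45-fold higher. Its second probe set was under the floor on both arrays. Hhip, which encodes a hedgehog-binding protein and is itself induced by the pathway, was 3.75-fold higher, from 82.7 to 310. Its other 3 probe sets were under the floor in wild type and gave bounds with log2 ratios of 0.66 to 0.78. Gli1, a transcriptional effector and target of the pathway, was 1.82-fold higher, from 234 to 425, and Ptch1, the receptor and a target, 1.25-fold higher, from 3254 to 4060.

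Of the 13 measured hedgehog targets, 10 were higher and 3 lower, and their median log2 ratio was 0.21 (bootstrap SE 0.11), above 99.97% of random lists. The median fell on Foxf1, which read 75.6 in wild type, under the floor, and 90.2 in Hammer toe. Its ratio is thus a bound, and the next members by ratio were Bcl2 at 0.19 and Osr1 at 0.28. Osr2, a transcription factor of limb mesenchyme, was 1.71-fold higher. Foxf2, Osr1 and Bcl2 were 1.23-fold, 1.21-fold and 1.14-fold higher, and Foxf1 at least 1.15-fold. The 5 probe sets of Bcl2 ranged from -0.24 to 0.19. The cell cycle genes Mycn, Ccnd2 and Ccnd1 had log2 ratios of 0.05, 0.08 and -0.02. Hand2 and Grem1, which act with Shh in the early limb bud, were 1.39-fold and 1.08-fold lower, and the probe sets of Hand2 above the floor on both arrays had log2 ratios of -0.84 and -0.47. With the floor at the 75th percentile, which left 7 targets and removed Hhip and Gli1, the median was 0.08 and lay above 94.3% of random lists. Among 14 ligands and transduction components, the median was -0.02, 7 were higher and 7 lower. Apart from Shh, only Scube1 passed 1.5-fold there, with a log2 ratio of at least 0.86, while Smo, Gli2 and Gli3 stood at 0.00, -0.07 and -0.04. Of 7 measured genes in the chromosomal neighbourhood of Shh, including Shh itself, 4 were higher and 3 lower. Rnf32 and Lmbr1 had log2 ratios of 0.51 and 0.44, and Ube3c and Insig1 of -0.47 and -0.27. Other probe sets of Lmbr1 and Ube3c went the opposite way, to -0.41 and 0.30.

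**Figure D2:**
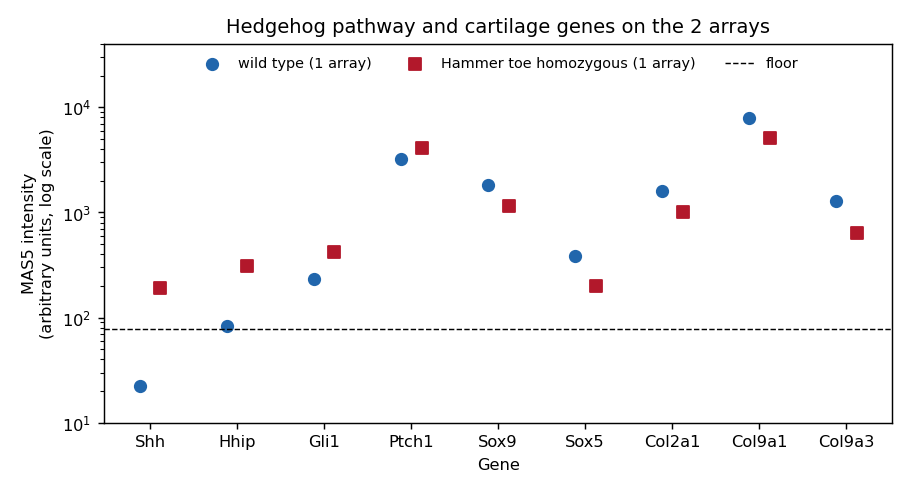
MAS5 intensity (y axis, arbitrary units, log scale) of 4 hedgehog pathway genes and 5 cartilage genes on the wild-type array (blue circles) and the Hammer toe array (red squares), 1 array each, with the floor of 78.1 as a dashed line. Shh, Hhip, Gli1 and Ptch1 are higher and Sox9, Sox5, Col2a1, Col9a1 and Col9a3 lower in Hammer toe.

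Cartilage genes formed the list that lay furthest below wild type. Of 16 measured members, 14 were lower in Hammer toe and 6 were at least 1.5-fold lower. The median log2 ratio was -0.51 (bootstrap SE 0.11), a 1.42-fold difference and below all 10000 random lists. Col9a3, a chain of the fibril-associated collagen of cartilage, was 1.99-fold lower, from 1273 to 641, and its measured probe sets had log2 ratios of -0.99 and -1.02. Sox9 and Sox5, transcription factors of chondrocyte differentiation, had log2 ratios of -0.64 and -0.96, and the 5 measured probe sets of Sox5 ranged from -1.29 to -0.30. Col2a1, the main collagen of cartilage, read 1608 in wild type and 1010 in Hammer toe. Col9a1 read 7936 and 5106, and Col11a1 1096 and 741, with a log2 ratio of -0.19 on its second probe set. Acan and Pth1r had log2 ratios of 0.23 and 0.03.

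The joint and tendon list did not follow cartilage as a whole, though its joint genes were lower. The list's median log2 ratio was 0.19 (bootstrap SE 0.22), above 99.21% of random lists, but above only 81.54% when all probe sets of a gene were averaged. The 4 members at 1.5-fold or more were Lum, Kera, Dcn and Egr1, at log2 ratios of 1.40, 0.99, 0.74 and 0.87. Lum, Kera and Dcn encode small proteoglycans that are also made by other connective tissues. The joint genes Gdf5, Erg and Wnt9a had log2 ratios of -0.09, -0.21 and -0.51, and the tendon genes Scx and Mkx of 0.16 and -0.13. Only 4 bone genes were measured, all higher, with a median of 0.16 and Col1a1 highest at 0.33. A second probe set of Col1a1 stood at -0.27.

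Among lists of interdigital regression, BMP signalling, cell death and matrix remodelling had medians inside the middle 95% of random lists. Single members lay further from wild type. Among 18 measured BMP signalling genes, 12 were lower and 6 higher, and none reached 1.5-fold on its brightest probe set with bounds counted at their bound. The BMP antagonist genes Nog, at least 1.33-fold lower, and Chrd, at least 1.31-fold higher, had 1 array under the floor and may differ by more. The median log2 ratio of the list was -0.06 (bootstrap SE 0.05), above 5.19% of random lists. The ligands Bmp2, Bmp4 and Bmp7 were at -0.19, -0.27 and -0.17, and the BMP target Msx2 at 0.05. Smad7, a feedback inhibitor, was at 0.08 on its brightest probe set and at -1.71 on the other, of the _x_at type. Bmper, a secreted BMP modulator, was 1.42-fold higher, from 1660 to 2356, where 95% of genes above 1000 lay within 1.24-fold. Among 19 cell death genes 10 were higher and 9 lower, none by 1.5-fold on its brightest probe set, with a median of 0.00 at percentile 47.77. Dapk1, a death-associated kinase, had the largest ratio, 1.23-fold higher, and a log2 ratio of 0.53 on its second probe set. The pro-apoptotic genes Bcl2l11 and Bmf were at 0.25 and -0.15, and Bmf was at 0.25 on its second probe set. In the matrix remodelling list, with a median of 0.08 at percentile 96.62, Tnc (tenascin C) was 1.62-fold higher. The proteases Adamts1 and Adamts5 were at -0.50 and -0.29, and Vcan, their substrate, at 0.08. Adamts1, from 1470 to 1041, also lay beyond the range of 95% of genes above 1000. The probe sets of Adamts5 ranged from -0.29 to 0.23 and those of Vcan from -0.15 to 0.13.

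Retinoic acid genes were slightly higher as a group. The median log2 ratio of 12 members was 0.22 (bootstrap SE 0.12), above all 10000 random lists, with 9 higher and 3 lower. Only Rbp4, a retinol carrier, passed 1.5-fold, at 1.52-fold. Rdh10, which makes retinal from retinol, was at 0.54, Cyp26b1, which degrades retinoic acid, at 0.38, and Crabp1, which binds it, at 0.37. Aldh1a2, the enzyme that makes retinoic acid in the interdigit, was at -0.19, from 13129 to 11474, and the receptor Rarg at -0.33.

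Other patterning and growth genes lay near wild type. The 18 genes of FGF signalling and the apical ridge had a median of -0.04 at percentile 15.97. Fgf8, the ridge ligand, was at -0.30, and Fgf10, a mesenchymal ligand, was 1.43-fold higher. Among 17 Wnt signalling genes, Dkk1 alone passed 1.5-fold on its brightest probe set, though another probe set of Sfrp1 was at 0.67 and others of Nkd2 and Ror2, under the floor in Hammer toe, had bounds of -0.80 and -0.95, and the Wnt target Axin2 was at 0.15. Their median was 0.05 at percentile 84.16. Of 23 distal Hox and limb patterning genes, 17 were lower, with a median of -0.06 at percentile 4.69, and in 5 of 9 alternatives the list lay below the middle 95% of random lists. Hoxa13 was at -0.41 and Hoxd13, at an intensity of 17291 in wild type, at -0.13. Tbx3 and Tbx2 were higher, by log2 ratios of 0.80 and 0.70, and the second probe set of Tbx3 was at 1.33. In 21 cell cycle genes the median was -0.04 at percentile 3.79, and Mki67, Top2a and Pcna stood at -0.04, -0.09 and 0.01. Ccne1 was 1.38-fold lower on a probe set of the _x_at type, and its ratio was -0.04 without such probe sets.

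Markers of other cell types differed between the samples. Surface ectoderm genes were higher in 13 of 15, with a median log2 ratio of 0.30 (bootstrap SE 0.07), above 99.99% of random lists. Cdh1, Perp and Esrp1 were at 0.49, 0.49 and 0.55. Krt14 was at -0.05 on its brighter probe set and at 0.40 on the other. Epcam was 1.49-fold higher on its brighter probe set and had a log2 ratio of -0.71 on the other, so that its mean over probe sets was -0.07. Pkp1 and Krt19, named above, are also expressed in epithelia. Macrophage genes were higher in 14 of 15, with a median of 0.33 (bootstrap SE 0.11) at percentile 99.94. Aif1 was 1.72-fold higher, and C1qa and Mrc1 were each at 0.59. With the floor at the 75th percentile only 4 macrophage genes remained, with a median of 0.04 at percentile 67.82. Muscle genes, at low intensity, were higher in 10 of 12, with a median of 0.43 (bootstrap SE 0.09) at percentile 99.98, and with a floor at the 25th percentile the median was 0.26 at percentile 97.33. Myh3, the embryonic myosin heavy chain, was 2.13-fold higher. Erythroid genes were lower in 7 of 8, with a median of -0.34 (bootstrap SE 0.14) at percentile 0.01, and Hbb-bh1, an embryonic globin, was 1.77-fold lower. The brightest member, Hbb-y, was at -0.04, with probe sets from -0.04 to 0.19, and Hbb-b2 was higher at 0.28. Of 15 listed genes, 5 had no probe set that named them alone. Endothelial genes had a median of 0.00 (8 higher, 8 lower), with Esam 1.46-fold higher. Schwann and nerve genes had a median of 0.18 at percentile 91.35, with Mbp 1.59-fold higher and at 0.22 on its second probe set.

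Early response and heat shock genes, which can mark handling, had a median of 0.05 at percentile 73.25, with Egr1 1.83-fold higher and Fos at -0.13. The sex-linked genes also differed. Eif2s3y, Uty and Kdm5d, which lie on the Y chromosome, had log2 ratios of 0.77, 0.65 and 0.48, and Xist, which is expressed from the inactive X, of -0.44. All 4 genes were above the floor on both arrays. Of the 22 lists, 2 lay below and 7 above the middle 95% of random lists.

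**Figure D3:**
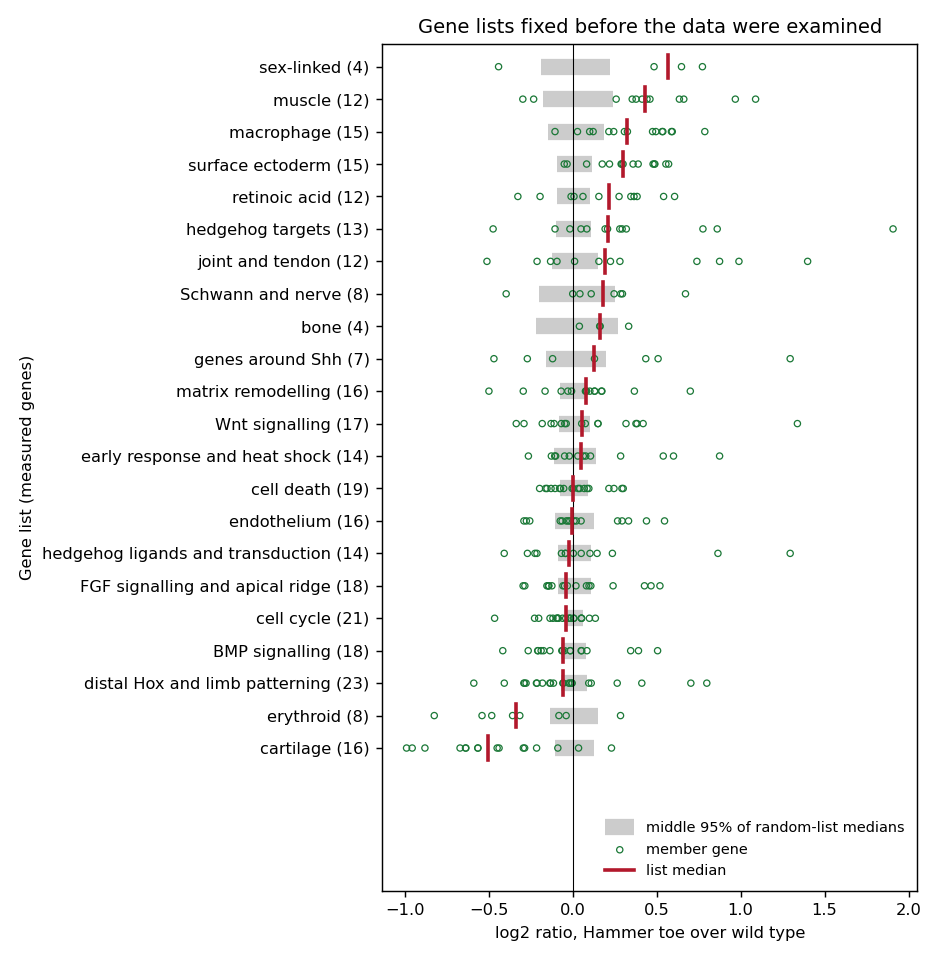
The log2 ratio of Hammer toe over wild type (x axis) for the members of each gene list (y axis, with the number of measured genes), with open circles for genes, red bars for list medians and grey bars for the middle 95% of medians of 10000 random lists matched on expression. The cartilage and erythroid medians lie to the left of the grey bars, at -0.51 and -0.34, and the hedgehog target median to the right, at 0.21.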

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

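Of 2525 measured probe sets without a single gene name, which stayed out of the gene comparison, 3 were at least 2-fold higher in Hammer toe and 8 at least 2-fold lower. Together they made up 0.436% of such probe sets, against 0.37% of named genes at 2-fold or more. The brightest of them read 1627 in wild type and 813 in Hammer toe. The 3 higher probe sets were all under the floor in wild type, and 4 of the 8 lower ones were under it in Hammer toe, so these ratios are bounds.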

How the results depend on the processing

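All alternatives here were planned. Median centring, quantile normalization and the lowess correction kept the 30 higher and 13 lower genes in the calls and added at most 3 lower genes. The counts of higher and lower genes were 1478 and 1521 with no floor, 397 and 385 with the floor at the 25th percentile, 5 and 1 at the 75th, and 16 and 6 with a pseudocount, of which 10 and 3 were among the reported genes. The mean over probe sets gave 25 and 10, with 24 and 8 of the reported genes, and leaving out _x_at, _s_at and _a_at probe sets gave 26 and 11, with 21 and 7. The share of higher calls, 69.8% in the reported setting, was 49.3% with no floor, 50.8% at the lower floor and 83.3% at the higher floor. At 1.5-fold the counts were 252 and 162, at 3-fold 2 and 1, and with 2 or more probe sets all past 2-fold 2 and 0. Cartilage had a median of -0.37 at the 25th percentile floor, hedgehog targets 0.0838 at the 75th and cell death 0.0555 without _x_at, _s_at and _a_at probe sets. The 6 main lists moved by less than their bootstrap SE in 51 cases and by more in 3. Cartilage stayed below the middle 95% of random lists in all 9 alternatives, retinoic acid above it in all 9 and hedgehog targets above it in 8 of 9. The genes around Shh ranged from percentile 1.59 to 99.91. The named genes moved by less than the SD between probe sets in 453 cases and by more in 63. None at 2-fold or more changed sign, while Epcam and Ccnd1 did in 1 alternative each. Among the hedgehog genes, Hhip ranged from 1.02 (mean over probe sets, with 3 of the 4 at a bound) to 1.91 and Shh from 1.28 to 3.09 (no floor). Without the 3 probe set types, Arhgap39 was at -0.23 and Afp had only a bound of -0.04, which leaves its difference undecided there. The low signal of most 2-fold genes over background limits them. No paired analysis was possible because each genotype has 1 array, and no array could be left out.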

Other observations

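The tests of digit tissue, mesenchyme share, ectoderm amount, embryo sex and the proteoglycan family were chosen after the values they use were seen. The others were written down before.

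Small leucine-rich proteoglycans of the matrix stood out among the higher genes. Of 13 family members 7 were measured, with a median log2 ratio of 0.74. Ogn, Lum, Kera and Dcn were at 1.45, 1.40, 0.99 and 0.74, Bgn (biglycan) at 0.34 and Fmod (fibromodulin) at 0.22 (probe sets from -0.07 to 0.60), while Podn (podocan) was lower at -0.93. A shift of the whole family is a hypothesis. A first test on all members was set aside after its result was seen, since most of them were already known to be higher. Only 2 measured members, Bgn and Podn, had not been seen when it was framed, and their median of -0.29 leaves it open. The interferon-inducible genes Iigp1 and Uba7 were also among the 2-fold higher genes, at log2 ratios of 1.04 and 1.06. A list of interferon-stimulated genes did not move with them: 13 measured members had a median of 0.0594 at percentile 69.79 of random lists. This argues against an interferon-type response only for the members read. Only 13 of 22 listed genes were measured, and Stat2, Oas1a, Psmb9 and Xaf1 had 1 array under the floor.

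Cartilage genes were lower in Hammer toe. A bias between the arrays that depends on intensity is argued against by the lowess correction, after which the median was still -0.50 and below all random lists. Less digit tissue in the dissected piece may account for the pattern. The 14 cartilage genes above the floor on both arrays had an SD 1.73 times that between probe sets of a gene, larger than in 95.7% of random lists, and the joint and tendon median was 0.19, or 0.07 with probe sets averaged, with the joint genes Gdf5, Erg and Wnt9a lower at -0.09, -0.21 and -0.51. None of these values excludes it. With 1 array per genotype, a smaller cartilage share, lower expression under the Hammer toe genotype and a difference of strain or between embryos cannot be told apart.

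Surface ectoderm genes were higher in Hammer toe. A lower share of mesenchyme was taken to raise endothelial markers like those of ectoderm. The endothelial median lay 0.30 below that of ectoderm (difference -0.30, SE 0.10 over list genes, not samples). Erythroid genes were lower (median -0.34), and macrophage and muscle genes were higher like ectoderm, at 0.33 and 0.43. The types thus moved apart, but this does not decide on a lower mesenchyme share, since vessels and blood may be lost together with mesenchyme. An intensity bias is argued against by the lowess correction, after which the ectoderm median was 0.29. More surface ectoderm in the mutant piece may be the cause, but this stays open: the SD of its 15 markers, 0.93 times that between probe sets of a gene, was larger than in 41.9% of random lists, so their evenness decides nothing. A change of expression under the genotype or a difference of strain is open and untested too.

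The Y-linked probe sets above the floor on both arrays were all higher (3 of 3, median log2 ratio 0.65) and those of Xist all lower (3 of 3, median -0.50). This is consistent with a higher share of male embryos in the mutant sample. Whether other differences follow the mix of sexes was not tested.

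A flanking segment of another strain around the Hammer toe locus could change probe binding near Shh. Among the 100 measured genes nearest to Shh in the gene order, 50 on each side, 7.0% differed by 1.5-fold or more (exact 95% interval 2.86% to 13.9%, counting error only), against 3.52% of the other genes. The ratio of 1.99 leaves this open. Hadhb, the only neighbour past 2-fold, was 2.34-fold lower on an _x_at probe set that read 4326 in wild type, while another of its probe sets had a log2 ratio of 0.40.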
